A study of Canis lupus familiaris with 4 samples.

How the data were processed

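Gene expression was measured in MDCKII cells, an established epithelial cell line from dog kidney, on 4 Affymetrix arrays. Per the labels, the cells either carried normal HIF1A (WT) or had HIF1A knocked down (KD), and all were kept for 24 h in normoxia before another 24 h in either normoxia or hypoxia. HIF1A encodes the oxygen-regulated subunit of a transcription factor that turns on genes of glycolysis and of the response to low oxygen. Each of the 4 groups had 1 array, so there is no replicate of any group. Biotinylated cRNA was made from 100 ng of total RNA with the 3' IVT Express kit, per the labels' protocols. How the knockdown was made and the oxygen level used are not given in the sources used here.

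The values are the intensity per probe set that the authors deposited, on a linear scale. The software, background correction and scaling that made these intensity values are not given in the sources used here. The deposited values show nearly equal means over probe sets after the lowest and highest 2% were left out, from 310 to 315 per array. Their sorted values differ between arrays, so the arrays were not brought to a common distribution. Between 1065 and 1129 values per array were exactly 1, and such a value was read as listed at 1, with no level. Detection calls were not used here.

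Values were turned to log2(intensity + 16), so differences understate the change of dim genes. Of 42924 probe sets, 29254 had 1 gene symbol, 439 had several and 13231 had none in the platform annotation used. Of those with 1 symbol, 27680 were found by gene ID in the RefSeq gene table of a German Shepherd assembly, used for names alone, and 0 symbols had to be updated. A gene was represented by its probe set with the highest mean over the 4 arrays, which gave 15115 genes. A gene was kept if its highest value reached the median of all log2 values, 5.96 (an intensity of 46.3), which left 9834 genes. No coordinates are given because no genome build was used.

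The 4 comparisons of 2 arrays and the difference of the responses, which is the labelled hypoxia minus normoxia difference in WT cells minus that in KD cells, have no residual degrees of freedom. They are given as values, with counts of genes that differ at least 2-fold. A linear scale had been foreseen, with that pseudocount. The 1 test that the arrays allow is an additive model of genotype and oxygen over all 4 arrays, fitted with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05. It has 1 residual degree of freedom, which holds the difference of the responses, and a prior of 8.11 degrees of freedom taken from other genes. Its p-values set a gene's mean difference against a variance taken mostly from that prior. That variance reflects how alike the pairs of differences were, over genes of like intensity, and not the spread between cultures.

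Before the data were examined, 37 gene lists were fixed. A list's median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays and not as a test. List medians used all measured members, also those below the floor. A further list of hypoxia genes, called the second hypoxia list, was written after HIF1A and the fixed lists had been seen and before its own values were. Which lists are described for which comparison was chosen after the list medians were seen. Intervals of list medians are 95% intervals from order statistics over member genes, which are not independent replicates.

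Named genes followed a rule fixed in advance. HIF1A came first. Each comparison and the difference of the responses gave the 10 genes with the largest differences in each direction above the floor, leaving out placeholder symbols. Each described list gave the 4 members with the largest absolute difference and any member with an absolute difference of at least 1 and the opposite sign to the list median. Each limma term gave the 10 smallest p-values per direction, and any member of the glycolysis and hypoxia response lists could be named.

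The steps were tested on simulated data with Python 3.11.15. In 9834 genes with errors drawn from the spread of the difference of the responses, 100 genes were made to differ 2-fold and 100 genes 4-fold between normoxia and hypoxia in both genotypes. The limma hypoxia term called 92 of the 100 genes with 2-fold changes, 100 of 100 with 4-fold changes and 9 of 9634 without a change. The 2-fold rule in WT cells counted 47 of the 100, 100 of 100 and 15 of 9634. These errors were normal and equal for genes of like intensity, a condition that favours the model. Among simulated lists of 25 genes, 50 of 50 shifted by 0.3 and 1 of 50 unshifted fell outside the 2.5th to 97.5th percentile.

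The alternatives were 3 other scalings (quantile, median centring, cyclic loess), the median over probe sets, 3 other floors, a 3-fold threshold, pseudocounts of 1 and 64, and a limma prior without a trend. For values with no test, a move by less than 1.5-fold was counted as the same, a tolerance chosen after the data were seen. Genes without a symbol entered no comparison.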

Results

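The series holds 4 arrays of dog MDCKII kidney epithelial cells, labelled WT normoxia, KD normoxia, WT hypoxia and KD hypoxia, with 1 array each. It asked how 24 h of hypoxia changes gene expression in these cells and how that depends on HIF1A. Median intensities were 47.1, 45.9, 47.0 and 45.6 in that order, and all pairs of arrays correlated across probe sets with Pearson's r from 0.982 to 0.987. With 1 array per group no difference has a replicate check, and the number of arrays limits the precision. Differences are log2 values throughout.

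HIF1A itself did not follow the knockdown label. Its intensity was 3651 in the array labelled WT normoxia, 3435 in the array labelled KD normoxia, 675 in the array labelled WT hypoxia and 625 in the array labelled KD hypoxia. The difference labelled KD minus WT was -0.09 in normoxia and -0.11 in hypoxia, while labelled hypoxia minus normoxia was -2.41 in WT and -2.43 in KD cells. A second HIF1A probe set read 135, 155, 27.6 and 21.6 in the same order. It was below the floor in both arrays labelled hypoxia, so the size of its differences is not measured. HIF1A fell in the limma hypoxia term by 2.42 (SE 0.08, adjusted p = 4.44e-07), and its genotype term was -0.10 (adjusted p = 0.494). HIF1A mRNA thus went against the knockdown label and differed by the oxygen label, so every direction below is that of the labels only.

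**Figure D1:**
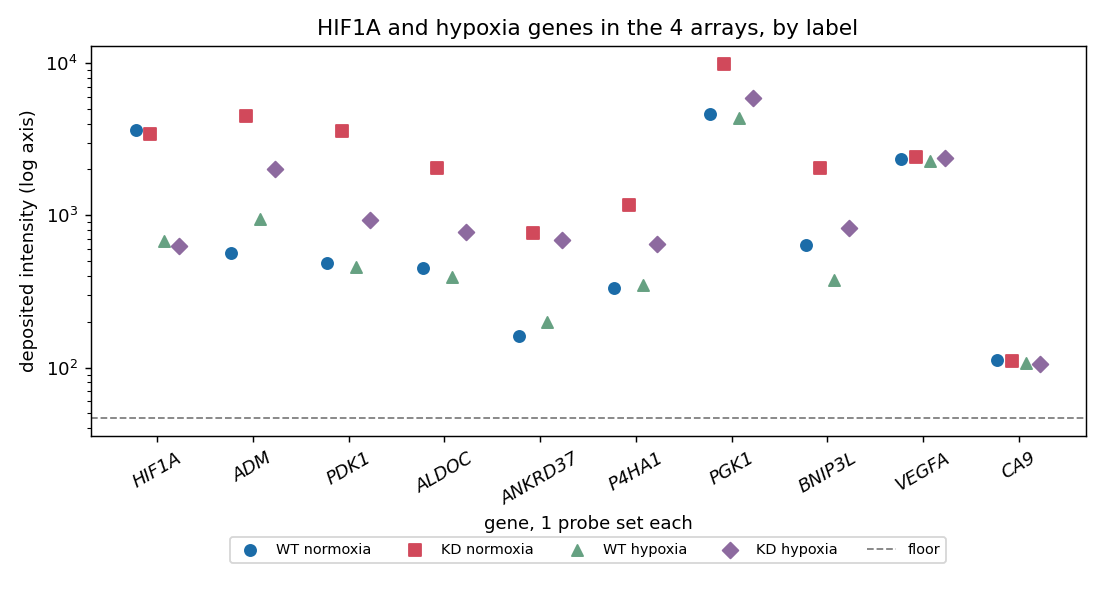
Deposited intensity (log axis) of HIF1A and 9 hypoxia or glycolysis genes in each of the 4 arrays, by label, with 1 point per array and the floor at 46.3 as a dashed line. HIF1A is low in the arrays labelled hypoxia (675 and 625), and ADM is highest in the array labelled KD normoxia (4486), while VEGFA and CA9 are close to equal in all 4.

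Between the arrays labelled WT hypoxia and WT normoxia, SPINK5, a serine protease inhibitor of epithelia, was higher by 5.74, the chemokine CXCL10 by 2.73, the matrix protein TGFBI by 2.64, EFEMP1 by 2.13 and the tryptophan-degrading enzyme IDO1 by 2.02. Lower were the metalloreductase STEAP2 (-3.05), the collagenase MMP13 (-3.05), the chemokine CCL2 (-3.00), the desmosomal cadherin DSG3 (-2.76), S100A4 (-2.12), SNAI2 (-2.05) and the integrin ITGA6 (-2.02). In all, 59 genes were at least 2-fold higher and 56 at least 2-fold lower among 9834. SOCS1 was listed at 1 in 3 arrays and at 417 in the array labelled WT hypoxia, so no fold is given. TGFBI (20.4 in normoxia) and STEAP2 (43.9 in hypoxia) were below the floor in 1 array of the pair, so the size of their differences is not measured. Other STEAP2 probe sets were at -1.02, above the floor in both arrays, and at -1.26. POLR3G, higher by 2.93, has another probe set that differed by 0.03.

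Groups of genes differed in the same pair. Of 30 measured members of the inflammation and NF-kappaB list, 23 were lower and 7 higher (median -0.28, below all 10000 random lists), with CCL2 leading. CXCL8 (45.4 and 7.44), LCN2 and TNFAIP2 were below the floor in both arrays, so no difference is given. Of 35 interferon-stimulated genes, 25 were higher and 10 lower (median 0.21, above all random lists), with IFI44L at 0.99 and MX1 at 0.76, while ISG20 was at -1.02. The interferon list had a median of 0.12 in the KD pair (96.0th percentile), and for labelled KD minus WT of 0.21 in normoxia (above all random lists, 28 of 35 higher) and 0.14 in hypoxia (99.96th percentile, interval -0.018 to 0.24). The NRF2 and antioxidant list had a median of 0.12 (99.6th percentile), with GCLC, which makes glutathione precursors, at 1.11, NFE2L2 at 0.48 and TXNRD1 at 0.47, against ABCC2 at -0.69 (36.5 in hypoxia, below the floor). Of 37 extracellular matrix genes, 21 were lower and 16 higher (median -0.17, below all random lists), with PLAU at -1.03 and MMP14 below the floor in every array. Over the 26 matrix genes above the floor the median was -0.07, the interval over all members was -0.31 to 0.05, and in the KD pair the median was 0.08 (22 higher and 15 lower). Glycolysis (median -0.04, 7.45th percentile) and the other hypoxia response genes (median 0.00, mean -0.04, 37.8th percentile) did not stand apart from random lists.

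Between the arrays labelled KD hypoxia and KD normoxia, SPINK5 had an intensity of 33.0 in normoxia and 3110 in hypoxia. IDO1 was higher by 2.94, CXCL10 by 2.71 and EFEMP1 by 2.63. MMP13 (-4.07), STEAP2 (-3.42), CCL2 (-2.97), DSG3 (-2.93) and TFPI2 (-2.63) were lower. STEAP2 (40.0) and TFPI2 (11.6) were below the floor in hypoxia, so the size of their differences is not measured. Other STEAP2 probe sets were at -0.96, above the floor in both arrays, and at -2.02. There were 55 genes at least 2-fold higher and 98 at least 2-fold lower. Of these, 23 higher and 31 lower genes were shared with the WT pair, against 0.330 and 0.558 for independent lists. The pairs share no array, and their differences correlated across genes with r = 0.52 and rho = 0.43, with genes not being independent replicates.

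Here the fixed glycolysis and hypoxia response lists were lower in the array labelled hypoxia, while the second hypoxia list had a median of -0.05 (12.7th percentile, interval -0.25 to 0.13, 17 lower and 10 higher) and did not stand apart. Of 26 glycolysis and lactate export genes, 21 were lower and 5 higher (median -0.42, below all random lists). PDK1, which restrains the conversion of pyruvate to acetyl-CoA, was at -1.93, ALDOC at -1.38, PFKFB3 at -1.27 and GAPDH at -1.14. Of 39 other hypoxia response genes, 28 were lower and 11 higher (median -0.33, below all random lists), with CP at -1.39 and BNIP3L at -1.29. EGLN3, a prolyl hydroxylase, was at -1.86, but read 16.1 in hypoxia, below the floor, so the size of its difference is not measured. RCOR2, higher in hypoxia, lay below the floor in every array. The inflammation list had a median of -0.28 (0.01th percentile, interval -0.48 to 0.06), with CCL20 at -0.89 and TLR2 below the floor in every array. CXCL8 had an intensity of 57.8 in normoxia and was listed at 1 in hypoxia, so no fold is given.

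**Figure D2:**
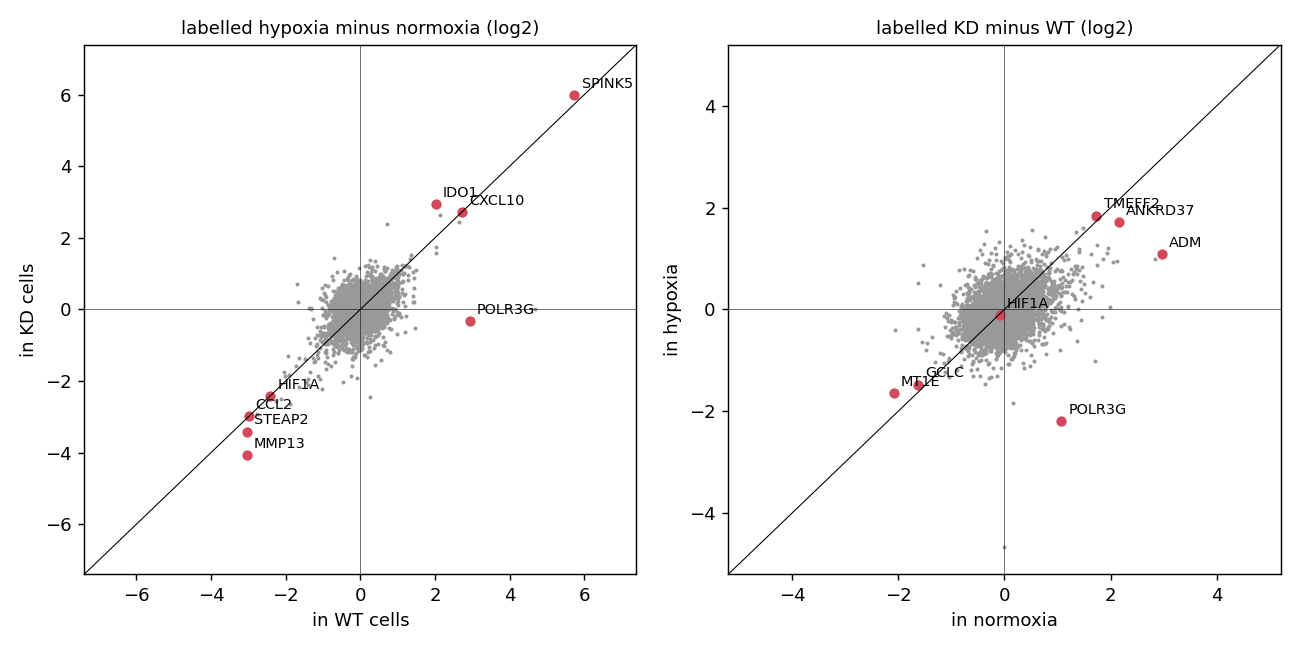
Log2 differences of 9834 genes above the floor, with 1 point per gene, named genes in red and the line of equal values. Left, labelled hypoxia minus normoxia in WT cells (x) and KD cells (y), where HIF1A lies at -2.41 and -2.43 and CXCL10 at 2.73 and 2.71. Right, labelled KD minus WT in normoxia (x) and hypoxia (y), where HIF1A lies at -0.09 and -0.11.

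The array labelled KD normoxia exceeded the array labelled WT normoxia in hypoxia and glycolysis genes. ADM, a vasodilator peptide, was higher by 2.96 (intensity 563 and 4486), PDK1 by 2.83, ANKRD37 by 2.15, ALDOC by 2.13, the carbonic anhydrase CA14 by 1.93 and the collagen prolyl hydroxylase P4HA1 by 1.75. Lower were the metallothionein MT1E (-2.09), GCLC (-1.62), IDO1 (-1.55) and ZNRF3 (-1.31). In all, 84 genes were at least 2-fold higher and 32 at least 2-fold lower.

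By list, 21 of 26 glycolysis genes were higher and 5 lower (median 0.39), among them GPI (1.66) and PFKL (1.47), and 30 of 39 other hypoxia response genes were higher and 9 lower (median 0.52), among them BNIP3L (1.64). CA9 (-0.02) and VEGFA (0.06), both widely used hypoxia markers, differed little. Cholesterol biosynthesis had 17 of 19 genes higher (median 0.34), with TM7SF2 at 0.76, EBP at 0.61, INSIG1 at 0.51 and HMGCS1 at 0.48. These 3 medians lay above all 10000 random lists. Ribosome biogenesis had a median of -0.25, below all random lists, with NOB1 at -0.91, WDR74 at -0.61, NOP56 at -0.52 and DDX21 at -0.45.

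Between the arrays labelled KD hypoxia and WT hypoxia TMEFF2 was higher by 1.84, ANKRD37 by 1.72 and the secreted growth factor binding protein FGFBP1 by 1.60. ADM was higher by 1.09 and BNIP3L by 1.09, and MT1E (-1.64) and GCLC (-1.48) were lower. Other TMEFF2 probe sets were higher by 1.77 and 0.32 in this pair, and by 1.55 and 0.36 in the normoxia pair. There were 51 genes at least 2-fold higher and 35 at least 2-fold lower, of which 14 and 7 were shared with the normoxia pair, against 0.436 and 0.114 for independent lists (r = 0.43, rho = 0.43 across genes, no shared array). The hypoxia response list had a median of 0.20 and cholesterol biosynthesis of 0.34 with FDFT1 at 0.54, both above all random lists, and glycolysis of 0.15 (99.95th percentile, interval -0.0075 to 0.33) with PDK1 at 1.00, ALDOC at 0.94 and PFKL at 0.83. PKM and EPO, lower in the array labelled KD hypoxia, lay below the floor in every array.

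The 84 genes picked as higher in the normoxia pair had a median of 1.27 there and 0.53 in the hypoxia pair. The 51 genes picked as higher in the hypoxia pair had a median of 1.13 there and 0.53 in normoxia, so the difference was smaller in the other pair whichever pair the genes were chosen in.

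The labelled hypoxia response differed between WT and KD cells by at least 2-fold for 154 genes, 86 with a larger value in WT cells and 68 with a larger value in KD cells. Glycolysis had a median difference of the responses of 0.38 and the hypoxia response list of 0.37, both above all random lists. ADM (1.87), PDK1 (1.83), ALDOC (1.18), GPI (1.13) and PFKFB3 (1.12) were among their members. Outside these lists POLR3G was at 3.25 in 1 probe set and 0.11 in another. KDM7A was at -1.88, but read 18.4 in the array labelled WT hypoxia, below the floor, so the size of its difference was not measured. ZNF275, CDC42SE1, ADAMTS3 and MFSD13A were also among these 154 genes, but lay below the floor in 2 or 3 of the 4 arrays, so the size of their difference was not measured. This difference keeps its value if the array labelled KD normoxia and the array labelled WT hypoxia change places. The difference was not tested, and with a floor at the 75th percentile 17 genes had a larger value in WT cells and 4 in KD cells.

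In the limma model, 464 genes rose and 410 fell in the labelled hypoxia term, and 289 rose and 239 fell in the genotype term. If the array labelled KD normoxia and the array labelled WT hypoxia change places, the hypoxia and genotype terms trade their values and calls. SPINK5, below the floor in the array labelled KD normoxia (33.0), rose by 5.87 (SE 0.11, adjusted p = 8.48e-09) and CCL2 fell by 2.98 (SE 0.10, adjusted p = 6.64e-07) with labelled hypoxia. In the genotype term FGFBP1 rose by 1.54, TMEFF2 by 1.79, CCL17 by 1.12, S100A2 by 1.30 and PTGS2, a prostaglandin synthase, by 0.85, and MT1E fell by 1.86, GCLC by 1.55 and the quinone reductase NQO1 by 1.01. The counts depend on the prior. Without its intensity trend, limma called 7 genes for hypoxia (SPINK5, CXCL10, TGFBI, HIF1A, CCL2, STEAP2 and DSG3) and 0 for genotype, for which 2196 genes had an unadjusted p under 0.05 with the trend. Without the floor limma called 77 and 0.

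In the limma genotype term 9 of 24 tested glycolysis genes rose and 0 fell (13 and 0 adjusted over the list alone). Of 33 other hypoxia response genes 14 rose and 1 fell (17 and 2 adjusted over the list alone), and of 17 cholesterol genes 9 rose and 0 fell (13 and 0 adjusted over the list alone). In the hypoxia term 12 of 33 interferon-stimulated genes rose and 1 fell (13 and 2 adjusted over the list alone), and of 17 inflammation genes 2 rose and 8 fell (2 and 10 adjusted over the list alone). All genotype calls end without the prior's trend or without the floor, and of the hypoxia calls in these lists those of CXCL10 and CCL2 stay without the trend.

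**Figure D3:**
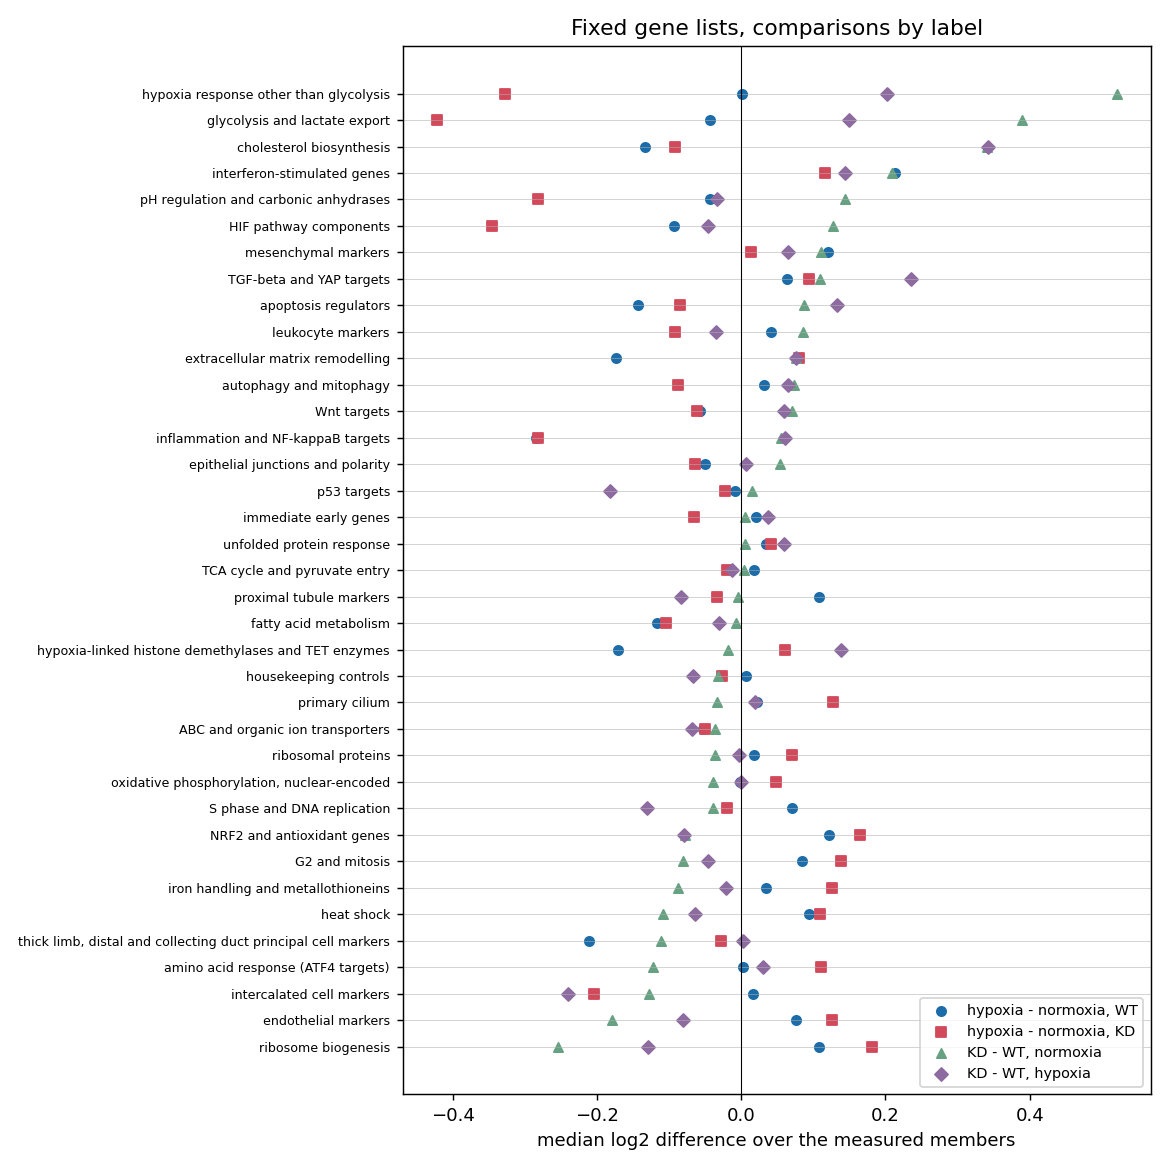
Median log2 difference over the measured members of each of the 37 fixed gene lists, with 1 point per list and comparison, comparisons by label. The hypoxia response list lies at 0.52 for KD minus WT in normoxia and at -0.33 for hypoxia minus normoxia in KD cells.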

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

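The test of probe sets and the counts by size were chosen only after the result was seen.

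Of 116 named genes, 48 had opposite signs of a labelled difference: 37 between the hypoxia responses of WT and KD cells and 30 between the genotype differences in normoxia and hypoxia. The differences were not tested, since each group has 1 array, and measurement error by itself gives small values of opposite sign. Some of the genes were named for a large difference of the responses, which favours opposite signs by that choice. The count is therefore not a rate among all genes. At least 1.5-fold each way were 17 of these genes, and at least 2-fold each way 2, POLR3G and ZNF275. ZNF275 read 18.2 and 1.06 in the arrays labelled hypoxia, both below the floor. The other POLR3G probe set above the floor had no opposite sign between the KD minus WT pairs (1.08 and 0.97), and its difference of the responses was 0.11. The values that follow, alphabetical within each group, are the log2 response to labelled hypoxia in WT cells minus that in KD cells. Above the floor in all 4 arrays were ADM (1.87), ANKRD37 (0.44), CCDC32 (-0.82), CDK20 (1.98), CLCN4 (1.38), DDX21 (-0.23) and DSG3 (0.17). Also above it in all 4 were FAM107B (-1.42), GPI (1.13), ITGA6 (-0.15), MTFR1 (-1.04), MTHFD2L (-1.54), MX1 (0.44) and NARF (-0.047). The others above it in all 4 were NOP56 (-0.36), P4HA1 (0.87), POLR3G (3.25), RAB11FIP1 (-1.04), RBM47 (-1.63) and WDR74 (-0.49). Each value is that of 1 probe set. Other probe sets that reached the floor gave far less for CDK20 (0.02 and 0.60), CCDC32 (-0.07), RBM47 (-0.10) and RAB11FIP1 (0.04 and -0.14). They kept the sign for CLCN4 (0.97), ANKRD37 (0.58) and P4HA1 (0.31 and 0.54). Of the 48 genes, 28 lay below the floor in at least 1 array and 20 in at least 3. For these 28 the value is the arithmetic result of the deposited intensities, its size is not measured, and no order is read from it. Below the floor in 1 or 2 arrays were ABCC2 (0.78), C6H16orf71 (-1.70), CYB561A3 (-1.24), DMD (0.72), KDM7A (-1.88), MFSD13A (-2.15), NFKBIE (0.29) and STEAP2 (0.37). Below the floor in at least 3 arrays were ADAMTS3 (-2.41), ATP1A4 (-1.67), BANF2 (1.99), CAMK2A (-1.64), CDC42SE1 (1.99), CXCL8 (0.73) and DES (1.08). So were EGLN3 (1.61), ENOSF1 (1.95), EPO (1.92), KIF3B (-1.52), LCN2 (-0.64), LLGL2 (1.85) and MMP14 (-1.79). The rest of these were PKM (0.65), RCOR2 (-1.59), SCML2 (-1.51), TLR2 (-0.59), TNFAIP2 (-0.37) and ZNF275 (2.70). EPO and CXCL8 were listed at 1 in the array labelled KD hypoxia, so their values contain no measured level there.

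Among 6424 probe sets above the floor that have no gene name and entered no comparison, 41 were at least 2-fold higher and 23 at least 2-fold lower with labelled hypoxia in both genotypes. In both labelled KD minus WT pairs, 10 were at least 2-fold higher and 7 lower.

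The genes whose labelled response differed at least 2-fold between WT and KD cells could be noise of single probe sets. Other probe sets of these genes had the same sign in 20 of 24 cases (83.3%, exact 95% interval 62.6 to 95.3). That argues against noise as the whole source, although those probe sets cover 21 of the 154 genes. Of the 24, 12 had the same sign and reached 0.5, and r across all other probe sets was 0.20. The interval treats probe sets as independent, though some belong to 1 gene. For labelled KD minus WT in hypoxia the same sign came in 21 of 30 (70.0%, interval 50.6 to 85.3), against 86.4% to 90.9% in the other pairs of arrays. A response to oxygen that depends on HIF1A had to put the second hypoxia list above the central 95% of random lists. The list lay at percentile 38.4 (median -0.02), so the prediction written beforehand was not met. Of its 27 members 19 reached the floor, and that median is the value of a member below the floor in every array. The 95% interval of the list median, -0.25 to 0.12, was brought in after that percentile was seen. It just reaches the bound of random lists at 0.11, so the explanation stays open. The fixed glycolysis and hypoxia response lists, which had shown the pattern, lay above all random lists.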

How the results depend on the processing

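The alternatives were listed before the data were examined, except those for the second hypoxia list. The 1.5-fold tolerance for values with no test was chosen after the data were seen.

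The counts of genes at 2-fold, in the order hypoxia in WT cells, hypoxia in KD cells, KD in normoxia, KD in hypoxia and difference of the responses, were 115, 153, 116, 86 and 154. Without a floor they were 183, 245, 178, 176 and 540, and with a floor at the 75th percentile 62, 75, 63, 29 and 21. With a floor on the mean of the arrays the last 2 were 56 and 65. At 3-fold they were 26, 33, 23, 7 and 22, with a pseudocount of 1 they were 211, 263, 220, 186 and 314, and with 64 they were 44, 63, 50, 21 and 24. The floors and pseudocounts change how dim genes enter, and the 3-fold threshold is stricter by construction. Of the 154 genes whose response differed, 21 passed the higher floor, so signal over background limits that count. Of those 154, 86 were larger in WT and 68 in KD cells, against 17 and 4 with that floor and 18 and 6 with a pseudocount of 64. Hypoxia in WT cells gave 59 higher and 56 lower genes, and 9 and 17 at 3-fold.

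The limma counts were 874 for hypoxia and 528 for genotype. Quantile normalization gave 1517 and 1311, and cyclic loess gave 932 for genotype. No floor gave 77 and 0, and a prior without a trend gave 7 and 0. The cause was not tested. Centring the arrays moved the share of higher genotype calls from 54.7% to 65.6% (486 of 741), and the median over probe sets to 47.3% (328 of 693). For hypoxia the share was 53.1%, and 48.9% with quantile and 47.4% with cyclic loess normalization. The limma adjusted p of HIF1A for hypoxia ranged from 3.59e-153 (quantile) to 0.0384 (no trend). The prior had 8.11 degrees of freedom in the main fit, 3.58 without a floor and 2.75 without a trend. It had 15.4 with cyclic loess and 18.1 with the median over probe sets. With quantile normalization it was infinite, so that fit treated the variance as known and its p-values do not reflect 4 arrays. No scaling moved the median of all genes by over 0.1.

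For HIF1A the median over probe sets falls on its second probe set, below the floor in both arrays labelled hypoxia. With the median over probe sets, HIF1A was at -1.80 for hypoxia in WT cells, a size not measured, and at 0.18 for KD in normoxia. There, too, signs turned for KIDINS220 (KD in hypoxia, -0.40), SCML2 (difference of the responses, 0.12), SH3BP5 (limma hypoxia term, 0.23), UGT1A6 (limma genotype term, 0.022), S phase genes (difference of the responses, -0.0092) and mesenchymal markers (hypoxia in WT cells, -0.059). The cause was not tested.

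Of 918 values of named genes, 775 moved by less than 1.5-fold, 141 moved more and 2 changed sign. Of 399 values of genes named from limma, 343 kept direction and call, 54 lost the call and 2 changed sign, and of 1330 list medians 1328 did not change a called sign. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The additive limma model compares within genotype and within oxygen, with 1 residual degree of freedom. Leaving out arrays was not possible either.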

Other observations

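The tests of HIF1A probe sets, scaling, other cell types and a fixed difference between populations were chosen after the results were seen. The other tests here had their prediction written before.

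In the limma hypoxia term, the glutaredoxin GLRX rose by 1.10 (SE 0.08, adjusted p = 0.000125) and the quinone reductase CRYZ by 1.07 (SE 0.08, adjusted p = 0.000128). The small heat shock protein HSPB1 fell by 0.96 (SE 0.06, adjusted p = 1.92e-05). With the KD label, the stress-induced gene ZFAND2A fell by 1.00 (SE 0.08, adjusted p = 0.000725) and the phospholipid transporter ABCB4 rose by 1.06 (SE 0.10, adjusted p = 0.00165) in limma. The hypoxia calls of GLRX, CRYZ and HSPB1 and both genotype calls were lost without the prior's trend (highest limma adjusted p 0.109 and 0.232).

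By percentile, other lists also stood apart from random lists. TGF-beta and YAP targets had a median of 0.23 for labelled KD minus WT in hypoxia (99.99th percentile, 14 of 22 higher, interval -0.032 to 0.35), and S phase genes of -0.13 (0.09th percentile, 25 of 32 lower). Apoptosis regulators had a median of -0.14 for labelled hypoxia in WT cells (0.37th percentile, interval -0.26 to 0.033) and fatty acid metabolism of -0.12 (0.305th percentile). HIF pathway components had a median of -0.35 for labelled hypoxia in KD cells (0.05th percentile, 10 of 12 lower), and pH regulation of -0.28 (0.1th percentile, interval -0.55 to 0.061). Housekeeping controls were within 0.07 of 0 in each pair, with medians of 0.01, -0.03, -0.03 and -0.07. Between 10 and 13 of 38 lists lay outside the central 95% of random lists per comparison, against 1.9 for lists of unrelated genes. The lists hold related genes and share members, unlike random lists, so 1.9 is no expected count for them and no test.

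HIF1A differed by the oxygen label and not by the knockdown label. The fixed glycolysis and hypoxia response lists stood out most in the array labelled KD normoxia. Their medians for labelled KD minus WT were 0.39 and 0.52 in normoxia, and 0.15 and 0.20 in hypoxia. For labelled hypoxia they were -0.04 and 0.00 in WT cells, and -0.42 and -0.33 in KD cells. CA9 and VEGFA differed little in any pair. A fault of 1 HIF1A probe set and unequal scaling were argued against, since a second probe set differed by -1.80 in WT and -2.19 in KD cells and the difference nearest to 0 under 3 scalings was -2.41. That second probe set was below the floor in both arrays labelled hypoxia, so its direction counts here and its size is not measured. For a response of WT cells under the labels as given, the second hypoxia list had to lie above the central 95% of random lists. It lay at percentile 0.42 for labelled hypoxia in WT cells, so that prediction was not met. The list was higher in the array labelled KD normoxia than in the array labelled WT hypoxia by 0.20 (95% interval 0.03 to 0.54, 21 of 27 members). Of the 27 members 19 reached the floor, and some of the 21 lay below it in every array. These values argue against such a response for this list only. A candidate explanation is that the labels of the arrays labelled KD normoxia and WT hypoxia are exchanged. For that, the list had to lie above the central 95% of random lists in labelled KD minus WT in normoxia. It lay at percentile 98.2. That margin is narrow, 14 members were higher and 13 lower, the interval of the median (-0.14 to 0.27) includes 0, and the groups keep their labels here.

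Cells of another type could bring the 54 genes, 23 higher and 31 lower, that differed at least 2-fold with labelled hypoxia in both genotypes, but no list of endothelial, leukocyte or mesenchymal markers lay outside the central 95% of random lists in both genotypes. The endothelial list came nearest, at percentile 74.0 in WT and 86.8 in KD cells, while the mesenchymal list lay at 97.53 in WT and 54.2 in KD cells. Members of these lists went both ways and 5 of 14, 9 of 18 and 18 of 37 lay above the floor in these cells, with VIM at 16968 and CD74 at 490 in the array labelled WT normoxia, so this stays open. A fixed difference between populations of cells predicts equal changes, and the median of the smaller over the larger change was 0.881. Choosing genes for 2-fold in both raises that ratio, and a change with oxygen that does not need HIF1A gives the same. If the labels of the arrays labelled KD normoxia and WT hypoxia are exchanged, both labelled hypoxia pairs compare KD with WT cells. A KD minus WT difference that does not depend on oxygen would then also give equal changes. HIF1A, at -2.41 and -2.43, is itself among the 54 genes. These explanations cannot be told apart.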
